A study of Rattus norvegicus with 3 samples.

How the data were processed

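Total RNA was taken from cultured rat granulosa cells in 3 groups, with 1 array each. Per the labels, follicles were punctured 48 h after PMSG, virus was removed after 2 h, stimulation began 24 h after infection and lasted 6 h, and RNA of 3 experiments was pooled before 5 ug were used for each Affymetrix rat genome array. The deposited values are MAS5 signals, an intensity per probe set on a linear scale; MAS5 is named in the submitters' processing notes and its version is not given in the sources used here. The table held 31099 probe sets, controls included, and the 2% trimmed mean of each deposited column was 500, so the authors' values had been scaled to a common trimmed mean. Detection calls and probe-level files were not used here. MAS5 subtracts mismatch signals, which makes low signals noisy, so a floor was used.

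The choices that follow, the gene lists and the rule for named genes were made before the data were examined, unless stated otherwise. Arrays were brought to the same 2% trimmed mean, which changed nothing of note. Signals below 126, the median over all probe sets and arrays, were set to that floor, and log2 was taken. A gene was represented by the probe set with the highest mean signal, and was measured in a comparison when at least 1 of its 2 arrays was above the floor. Where 1 array was below the floor, the fold is a bound and is given as at least that size. Differences of 2-fold or more were counted. No test is possible with 1 array per group, so no p-value is given, and the number of arrays limits the precision.

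Probe sets were named through the platform annotation. It gave 1 gene symbol for 20832 probe sets, several genes for 436 and none for 9831. Symbols were updated through Entrez IDs with the RefSeq gene table of assembly GRCr8, in which 20764 probe sets matched; this left 14218 genes, 4526 of them with 2 or more probe sets. Of 318 list entries, 290 matched a gene, 5 of them under a newer symbol, and the others were not analysed here. Genome coordinates are not given, since no genome was used here.

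The text names Nfil3; the 10 genes with the highest and the 10 with the lowest difference in each of the FSK/PMA and NFIL3 comparisons; and the 5 genes in each direction with the largest NFIL3 difference against their FSK/PMA difference. Such genes needed a signal of at least 4 times the floor, the same direction in all measured probe sets, and a symbol that is no placeholder. Of each of the 20 fixed lists, up to 4 members with the largest difference in the comparison described are named. Where other members are named, for comparison with the other contrast, they had been named by the rule there.

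A list with at least 5 measured members was described by its median difference and by the percentile of that median among 10000 random lists of the same size, matched on mean signal in 20 bins. It was called apart when it lay outside the central 95% of these. About 1 list in 20 passes these limits by chance if its genes vary independently. Genes that are regulated together can pass them more often, and with 1 array per group that rate could not be measured. Of 17 lists tested in the FSK/PMA comparison, 7 lay above and 2 below; some genes belong to several lists. Opposed differences were counted beside the number that independent sets would share and beside 100 simulations of unchanged genes with a common array.

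Signal quality was read from control probe sets. The 9 spiked hybridisation controls were 1.39 times as bright on the FSK/PMA array and 1.48 times as bright on the NFIL3 array as on the control array, after scaling. The 27 controls for transcripts that rat RNA lacks stayed below 47.7 on all arrays, under the floor. The 3' to 5' ratio of Gapdh was 1.28, 1.15 and 1.14 on the control, FSK/PMA and NFIL3 arrays, and that of hexokinase was 3.21, 5.04 and 2.98. Across probe sets, floored log2 signals correlated at 0.933 between control and FSK/PMA and at 0.986 between FSK/PMA and NFIL3; probe sets are not independent replicates. Technical error was estimated from genes with 2 measured probe sets, whose disagreement gave a robust SD per difference of 0.31 in the FSK/PMA comparison and 0.22 in the NFIL3 comparison. The probe sets differed in the same direction in 73.6% and 63.9% of these genes. Among differing genes with 2 or more measured probe sets, all agreed in direction for 209 of 216 higher and 277 of 296 lower with FSK/PMA, and for 22 of 23 and 28 of 30 with NFIL3. This spread leaves out differences between cultures.

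The code was tested on simulated data with known folds, over 14218 genes. In the simulated FSK/PMA comparison all 50 genes in each direction at 4-fold and at 8-fold were recovered, and 6 of 8928 unchanged genes passed 2-fold. The simulated NFIL3 comparison recovered the same numbers, and 0 of 8908 unchanged genes passed. Of 100 lists of randomly drawn genes, 4 and 2 lay outside the limits, which does not give the rate for genes that are regulated together.

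Alternatives covered the scaling (median of probe sets above the floor, quantile, cyclic loess with a span of 0.3 and 3 iterations), the floor (25th percentile, 75th percentile, none, or added as a pseudocount), the gene value (mean of all measured probe sets, or probe sets with suffixes for several transcripts left out), the fold (1.5 and 3), different probe sets in the 2 comparisons, and random lists that were not matched. Random lists matched on the FSK/PMA difference, and a count over genes whose probe sets agree in both comparisons, were added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.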

Results

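Gene expression was measured in primary granulosa cells of immature female Sprague-Dawley rats, 24 to 25 days old, collected 48 h after pregnant mare's serum gonadotropin (PMSG), a hormone preparation that brings follicles to the preovulatory stage. The cells were infected with an adenovirus carrying green fluorescent protein (Ad-GFP) or NFIL3 (Ad-NFIL3) at 50 pfu per cell. From 24 h after infection they were cultured for 6 h with 10 uM forskolin and 20 nM phorbol 12-myristate 13-acetate (FSK/PMA), which activate adenylyl cyclase and protein kinase C and stand in for the ovulatory gonadotropin signal. NFIL3 is a basic leucine zipper transcription factor known mainly as a repressor. There were 3 groups, Ad-GFP without FSK/PMA (the control array), Ad-GFP with FSK/PMA, and Ad-NFIL3 with FSK/PMA. Each had 1 Affymetrix rat genome array, hybridised with RNA pooled from 3 experiments. There were no replicate arrays, so differences below compare 3 pools and carry no p-value. The median signal over all probe sets was 127 on the control array, 115 with FSK/PMA and 136 with NFIL3 and FSK/PMA. Between 48.1% and 51.8% of probe sets were above the floor of 126.

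Nfil3 itself was read first, as a check of the labels. Its signal was 564 on the control array, 1321 with FSK/PMA and 5882 on the Ad-NFIL3 array, which was 2.34-fold higher with FSK/PMA and a further 4.45-fold higher with the NFIL3 virus. The array labelled Ad-NFIL3 thus had the highest signal. Nfil3 had 1 probe set on the array. Whether it lies in the part of the transcript that the virus carries is not known here; if it lies outside, its signal is no check of the virus, and if inside, viral and cellular transcript cannot be divided.

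The first comparison set Ad-GFP with FSK/PMA against Ad-GFP alone and asked which granulosa cell genes respond to the stimulus. Genes of the ovulatory response had some of the largest differences. Tnfaip6, which encodes a hyaluronan-binding protein of the expanding cumulus matrix, was at least 78.1-fold higher. Ptgs2, the inducible cyclooxygenase, was at least 52.8-fold higher, and Plat, tissue plasminogen activator, was at least 38.6-fold higher. The FSH-dependent follicle genes Inhbb, the inhibin beta B subunit, and Fst, follistatin, were 10.1-fold and 3.78-fold lower. Among 9395 measured genes, 698 were at least 2-fold higher and 1072 were at least 2-fold lower. Differences of 8-fold or more numbered 56 among the higher genes and 21 among the lower genes.

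The 10 most raised genes began with Fam110c, whose signal was 114 on the control array and 12704 with FSK/PMA, at least 101-fold higher. After Tnfaip6 came Penk, the enkephalin precursor, at least 55.8-fold higher, and then Ptgs2. Plk2, a polo-like kinase, was 48.7-fold higher, Nap1l5 was 48.3-fold higher, and Giot1, a gonadotropin-inducible zinc finger gene, was 36.9-fold higher. Ass1, argininosuccinate synthase, was 33.5-fold higher and Sult1e1, estrogen sulfotransferase, was at least 26.2-fold higher. Mmp11, a matrix metalloproteinase, was the most lowered gene, with signals of 3393 on the control array and 152 with FSK/PMA, 22.3-fold lower. Trib2 was 20.7-fold lower, Trim2 was 16.2-fold lower and Pik3ip1, an inhibitor of phosphoinositide 3-kinase, was 14.0-fold lower. Wnt5b was at least 12.8-fold lower, Hao2 was 12.2-fold lower, Cgnl1 was 10.9-fold lower, Flvcr2 was 10.8-fold lower and Rnf138l1 was at least 10.2-fold lower.

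**Figure D1:**
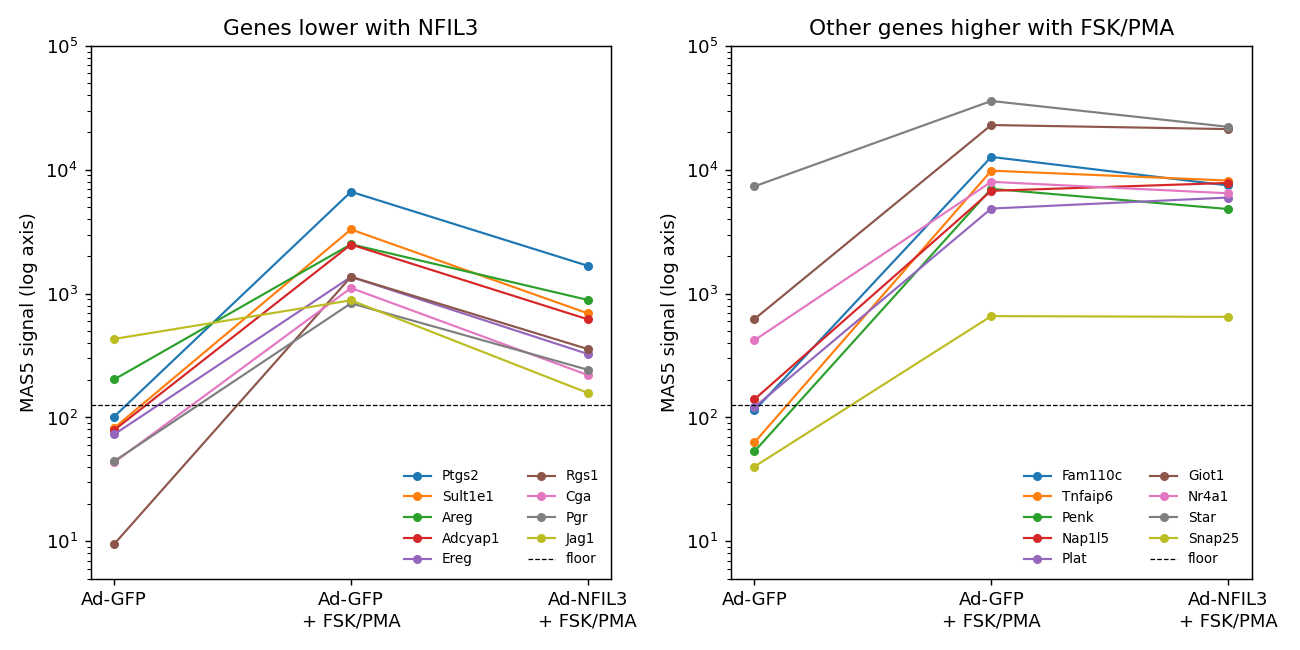
MAS5 signal (log axis) of 18 genes on the 3 arrays, 1 point per array, with the floor as a dashed line. Ptgs2 goes from 102 on the control array to 6644 with FSK/PMA and 1678 with NFIL3 and FSK/PMA, while Plat stays at 5967 with NFIL3; the genes are examples taken from those named in the text.

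Periovulatory genes, those induced in the follicle by the luteinizing hormone (LH) surge, stood highest of the lists. Of 17 measured, 11 were at least 2-fold higher and 2 were at least 2-fold lower, with a median log2 difference of 2.03, at percentile 100 among random lists of the same size and signal. Besides Tnfaip6, Ptgs2 and Plat, the transcription factor gene Runx1 was 19.8-fold higher. Immediate early and cAMP-responsive genes were higher in 16 of 19 cases and lower in 0, with a median of 1.65 at percentile 100. The nuclear receptor genes Nr4a1 and Nr4a3 were 19.0-fold and at least 18.7-fold higher, the phosphodiesterase gene Pde4b was at least 15.7-fold higher, and Crem was 8.50-fold higher.

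Steroid hormone genes differed in both directions. In the steroidogenesis list 7 of 15 genes were at least 2-fold higher and 4 were at least 2-fold lower, and the median of 0.81 lay at percentile 100. Over the settings this median ranged from 0.53 to 1.44. Cyp19a1, aromatase, was at least 19.8-fold higher. Scarb1, the lipoprotein cholesterol receptor, was 5.04-fold higher and Star, which carries cholesterol into mitochondria, was 4.89-fold higher, whereas Nr0b1, a repressor of steroidogenic transcription, was at least 9.59-fold lower. Cholesterol synthesis and uptake genes were higher in 7 of 17 cases and lower in 0, with a median of 0.92 at percentile 100. The largest differences in that list were those of Acat2 (3.33-fold), Nsdhl (2.72-fold), Sqle (2.58-fold) and Sc5d (2.55-fold).

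Of 16 measured genes that mark granulosa cells of the preovulatory follicle, 8 were at least 2-fold lower and 1, Cyp19a1, was higher; the median was -0.98, at percentile 0. With Inhbb and Fst, Nppc, the precursor of the peptide that holds oocytes in meiotic arrest, was at least 4.17-fold lower. Interferon-stimulated genes were lower in 6 of 14 cases, with a median of -0.58 at percentile 1.21. Their largest differences were those of Oas1a (4.08-fold lower), Irf1 (2.42-fold lower), Stat2 (2.33-fold lower) and Psmb8 (2.24-fold lower). This list did not stand apart with lower floors or without probe sets that can bind several transcripts, when its percentile was 12.0.

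Progesterone receptor dependent genes had a median of 0.80 at percentile 99.9, with 3 of 10 at least 2-fold higher. Snap25, a vesicle fusion gene, was at least 5.23-fold higher, Rgs2 was 4.12-fold higher and Edn2, endothelin 2, was at least 3.14-fold higher. Heat shock and oxidative stress genes had a median of 0.60 at percentile 99.7, with 3 of 11 at least 2-fold higher. Gclm, a subunit of the first enzyme of glutathione synthesis, was 4.15-fold higher, Srxn1 was 3.52-fold higher and Hsph1 was 3.08-fold higher. Cytokine, chemokine and NF-kB feedback genes had a median of 0.33 at percentile 98.6, with 3 of 9 at least 2-fold higher. Nfkbiz was at least 9.55-fold higher, Ccl2 was at least 2.91-fold higher and Il1r1 was 2.14-fold higher. With other scalings between arrays the percentile of this list was between 95.3 and 96.3, inside the limits.

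Lists whose medians lay inside the range of random lists still held large differences. In the prostaglandin list (median 0.13, percentile 74.6) the phospholipase gene Pla2g4a was 8.38-fold higher, while Ptges, a prostaglandin E synthase, was at least 5.80-fold lower and the transporter gene Abcc4 was 2.95-fold lower. In the extracellular matrix list (median 0.10, percentile 84.0), 6 of 18 genes were higher and 3 were lower. The protease gene Adamts4 was 13.9-fold higher, the urokinase receptor gene Plaur was 13.0-fold higher and Serpinb2 was at least 7.22-fold higher. The clock and PAR bZIP list (median -0.17, percentile 48.9), which holds genes that share binding sites with NFIL3, had 4 genes higher and 4 lower of 13, and stood above the range with a floor at the 75th percentile (median 0.50). Per1 was 5.09-fold and Bmal1 was 3.06-fold higher, and Dbp was at least 4.88-fold and Tef was 3.02-fold lower. In the cell cycle list (median -0.38, percentile 36.2) Aurka was 3.43-fold higher and Aurkb was at least 2.46-fold lower. In the unfolded protein and integrated stress response list (median 0.04, percentile 59.5), Asns, asparagine synthetase, was 22.0-fold higher and Atf4, the transcription factor of the amino acid response, was 2.40-fold higher.

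Markers of other cell types were read in the same way. Of 12 theca and stroma markers 6 were measured, with a median of -0.19 at percentile 29.4, and Col3a1 had the highest collagen signal, 395 on the control array. Leukocyte markers had a median of 0.04 at percentile 78.1, with Cd14 2.46-fold higher. Of 7 oocyte markers on the array only 1, Zp2, was measured, and the others were below the floor on both arrays. Zp2 was 2.20-fold lower, with a signal of 891 on the control array. Hbb, beta globin of red cells, had signals of 19442, 18005 and 15376 on the control, FSK/PMA and NFIL3 arrays. Housekeeping genes had a median of 0.32 at percentile 86.8, with Hprt1 2.34-fold higher. The median of all measured genes was -0.10 and moved to 0.00 when arrays were scaled to their median instead; the housekeeping median moved from 0.32 to 0.43. With that scaling 806 genes were higher and 882 were lower, and the higher share of the differing genes was 47.7% in place of 39.4%.

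The second comparison, Ad-NFIL3 against Ad-GFP, both with FSK/PMA, asked which genes of stimulated granulosa cells differ when NFIL3 is overexpressed. Of 17 measured periovulatory genes, 6 were at least 2-fold lower with NFIL3 and 11 were within 2-fold. Ptgs2 was 3.96-fold lower, with signals of 6644 without and 1678 with the NFIL3 virus. Ereg and Areg, which encode the epidermal growth factor-like peptides epiregulin and amphiregulin, were 4.19-fold and 2.82-fold lower, and Pgr, the progesterone receptor, was 3.44-fold lower. Tnfaip6, Plat and Snap25 had log2 differences of -0.26, 0.30 and -0.02, and a second, dimmer probe set of Tnfaip6 differed by -0.75. Among 9397 measured genes, 126 were at least 2-fold higher and 90 were at least 2-fold lower.

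The gene most lowered with NFIL3 was Jag1, a Notch ligand, with signals of 883 and 158, 5.60-fold lower. Cga, the glycoprotein hormone alpha subunit, was 5.04-fold lower, and Psat1, an enzyme of serine synthesis, was 4.98-fold lower. Sult1e1 was 4.76-fold lower and Wfdc10a was 4.57-fold lower. Adcyap1, which encodes the neuropeptide PACAP, was 4.02-fold lower and Rgs1 was 3.83-fold lower. Adamtsl1 stood highest, with signals of 111 and 940, at least 7.46-fold higher. Fn1, fibronectin, was 5.19-fold higher and Anpep, aminopeptidase N, was 5.11-fold higher. Angptl4 was 4.03-fold higher, Capn5 was 3.71-fold higher, the actin-binding protein gene Cald1 was 3.30-fold higher and the kinase scaffold gene Akap12 was 3.23-fold higher. Dimmer probe sets of Capn5 differed by 0.78 and at least 0.84 on the log2 scale. Nek6 and Ifitm3 were 3.20-fold and 3.12-fold higher.

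Of the 16 lists tested, 6 lay below the random range and 0 above it. Periovulatory genes had a median of -0.36 (-0.61 to -0.24 over the settings) at percentile 0, with 0 genes at least 2-fold higher. The prostaglandin list had a median of -0.34 at percentile 0.01. Its 2 genes past 2-fold were Ptgs2 and Hpgd, the prostaglandin-degrading dehydrogenase, which was 3.10-fold lower. Preovulatory follicle genes had a median of -0.31 at percentile 0.03, with 4 of 15 at least 2-fold lower. These were Hsd17b1, an estradiol-forming enzyme, at 3.07-fold lower, Inhba at 2.57-fold lower, Cyp19a1 at 2.51-fold lower and the LH receptor gene Lhcgr at 2.15-fold lower. Dimmer probe sets of Inhba and Lhcgr differed by -0.93 and -0.57 on the log2 scale. The unfolded protein and integrated stress response list had a median of -0.41 at percentile 0, although 0 of its 14 genes were past 2-fold. Atf4 was 1.93-fold lower, Asns was 1.61-fold lower, Chac1 was 1.49-fold lower and Herpud1 was 1.43-fold lower.

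Immediate early and cAMP-responsive genes had a median of -0.29 at percentile 0.01, with 1 of 19 lower and 1 higher past 2-fold. Nr4a3 was 3.34-fold lower and Egr2 was 2.51-fold higher, and Nr4a2 and Fosl2 were 1.84-fold and 1.82-fold lower. Dimmer probe sets of Nr4a3 differed by -1.52 and 0.06 on the log2 scale, the last near the floor. Heat shock and oxidative stress genes had a median of -0.19 at percentile 2.25, and lay inside the limits with quantile normalisation (4.85), cyclic loess and the mean of probe sets (5.44). In that list Gclm was 3.23-fold lower and the heat shock gene Hspa1a was 2.03-fold higher. Against random lists matched on the FSK/PMA difference, an alternative chosen after the data were seen, the percentiles of the periovulatory, immediate early and heat shock lists were 3.64, 24.5 and 14.2, inside the limits. The other 3 lists remained below them.

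**Figure D2:**
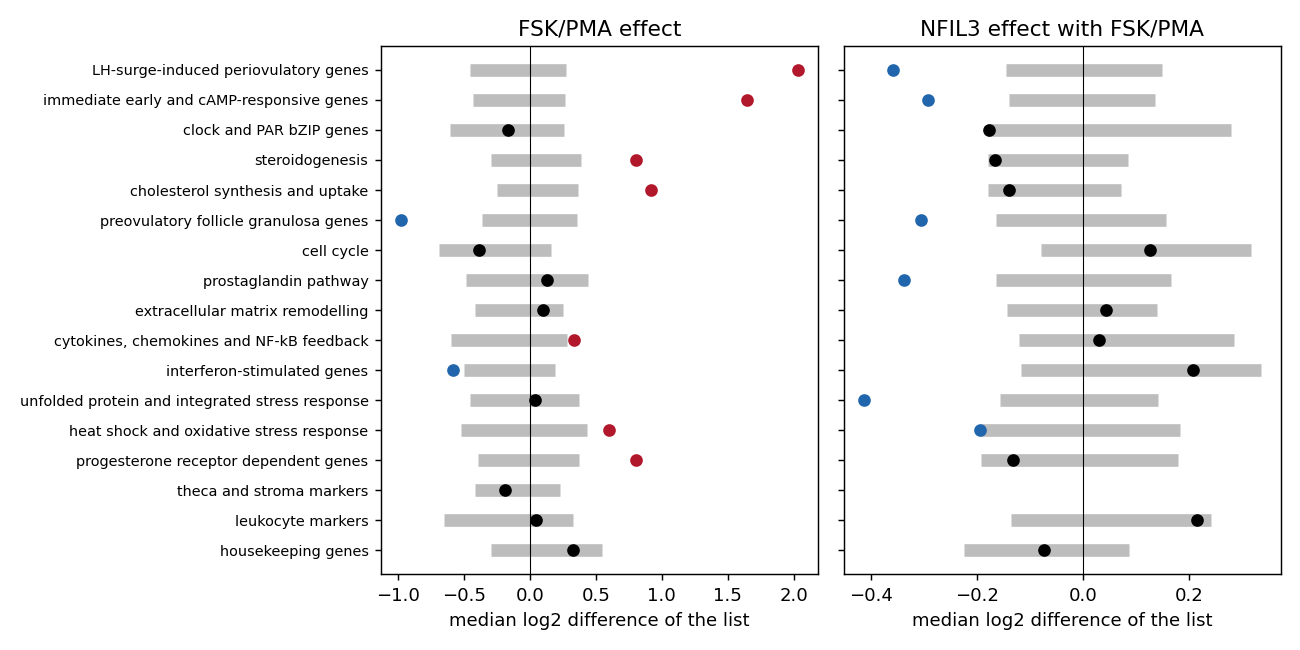
Median log2 difference of each gene list (points) in the FSK/PMA comparison (left) and the NFIL3 comparison (right), with grey bars for the central 95% of 10000 random lists matched on signal. Red and blue points lie above and below that range; the periovulatory list is at 2.03 on the left and -0.36 on the right.

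The remaining lists lay inside the random range in the main setting. Steroidogenesis genes had a median of -0.17 at percentile 3.55, where Por was 1.87-fold lower and Star was 1.62-fold lower. Clock and PAR bZIP genes had a median of -0.18 at percentile 2.78 and 0 of 10 past 2-fold. Cry2 was 1.90-fold lower, while Per2 and Tef were 1.77-fold and 1.69-fold higher. A second, dimmer probe set of Cry2 differed by -0.06 on the log2 scale. Cholesterol genes had a median of -0.14 at percentile 7.41, and the largest difference was that of Fdft1, 1.74-fold lower. A second, dimmer probe set of Fdft1 differed by -0.19 on the log2 scale. Progesterone receptor dependent genes had a median of -0.13 at percentile 8.92, with the protease gene Adamts1 2.05-fold lower. In the matrix list (median 0.04, percentile 74.0) Serpinb2 was 3.07-fold lower, Serpine2 was 2.77-fold lower and the metalloproteinase inhibitor gene Timp3 was 2.09-fold lower, while Mmp19 was 2.31-fold higher. Dimmer probe sets of Timp3 differed by -0.74, -0.80 and -0.09 on the log2 scale. In the cytokine list (median 0.03, percentile 27.9) the chemokine gene Ccl2 was 2.53-fold and Cxcl1 at least 2.77-fold higher. Interferon-stimulated genes (median 0.21, percentile 81.5) and cell cycle genes (median 0.13, percentile 53.2) had 0 members past 2-fold. Progesterone receptor dependent genes lay below the range with quantile normalisation (percentile 0.83), cyclic loess (1.98) and a floor at the 75th percentile (0.95), and clock genes did so with loess (2.42) and that floor (0.49). The steroidogenesis, cholesterol and matrix lists also lay below it under some settings, with percentiles from 1.21 to 2.36.

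Among markers of other cells, 4 theca and stroma markers were measured in this comparison, too few for a percentile. Dcn, decorin, was 2.45-fold higher with NFIL3, with signals of 196 and 481, and Col3a1 differed by 0.05 on the log2 scale. Leukocyte markers had a median of 0.21 at percentile 94.2, with 0 of 9 past 2-fold. Zp2, the only oocyte marker measured, was 1.51-fold lower. Of the endothelial markers, Kdr and Egfl7 were measured, with log2 differences of -0.38 and 0.19. Alas2, of red cells, differed by -0.10. Housekeeping genes had a median of -0.07 at percentile 40.0. The higher share of the differing genes was 58.3%, but quantile normalisation gave 91 higher and 112 lower (44.8%) and cyclic loess gave 87 higher and 112 lower (43.7%). A floor at the 25th percentile gave 545 higher and 236 lower, and one at the 75th percentile gave 36 and 48.

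The third comparison asked how far the NFIL3 differences ran against the FSK/PMA differences. Of the 698 genes at least 2-fold higher with FSK/PMA, 53 were at least 2-fold lower with NFIL3, where independent sets of these sizes would share 6.97. These made up 58.9% of the 90 genes lower with NFIL3, and those with the lowest NFIL3 values were Jag1, Cga, Sult1e1, Ereg and Adcyap1. Cga was at least 8.82-fold higher with FSK/PMA, Ereg at least 10.8-fold and Adcyap1 at least 19.8-fold, and Jag1 was 2.05-fold higher. In the other direction, 30 genes lower with FSK/PMA were higher with NFIL3, against 12.8 for independent sets. The second count was 19 with quantile normalisation and 18 with cyclic loess, and other treatments of the floor gave from 28 to 344 for the first and from 5 to 716 for the second. The 5 most raised of these were Anpep, Capn5, Akap12, Mier2 and Ifi27l2b. With FSK/PMA, Anpep was 2.51-fold lower, Capn5 was 4.36-fold lower and Akap12 was 4.35-fold lower, and Mier2 and Ifi27l2b were 2.49-fold and 2.42-fold higher with NFIL3. A second, dimmer probe set of Capn5 differed by -0.97 with FSK/PMA and 0.78 with NFIL3 on the log2 scale, both under 2-fold. Another was below the floor on the control and FSK/PMA arrays and differed by at least 0.84 with NFIL3. Differences in the same direction were shared by 14 higher genes, against 9.06, and 9 lower genes, against 9.86. A gene could be called lower with NFIL3 only with a signal of at least 2 times the floor on the FSK/PMA array. All genes called higher with FSK/PMA met this, but not all other measured genes did. The 6.97 is thus too low, by an amount that was not computed.

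**Figure D3:**
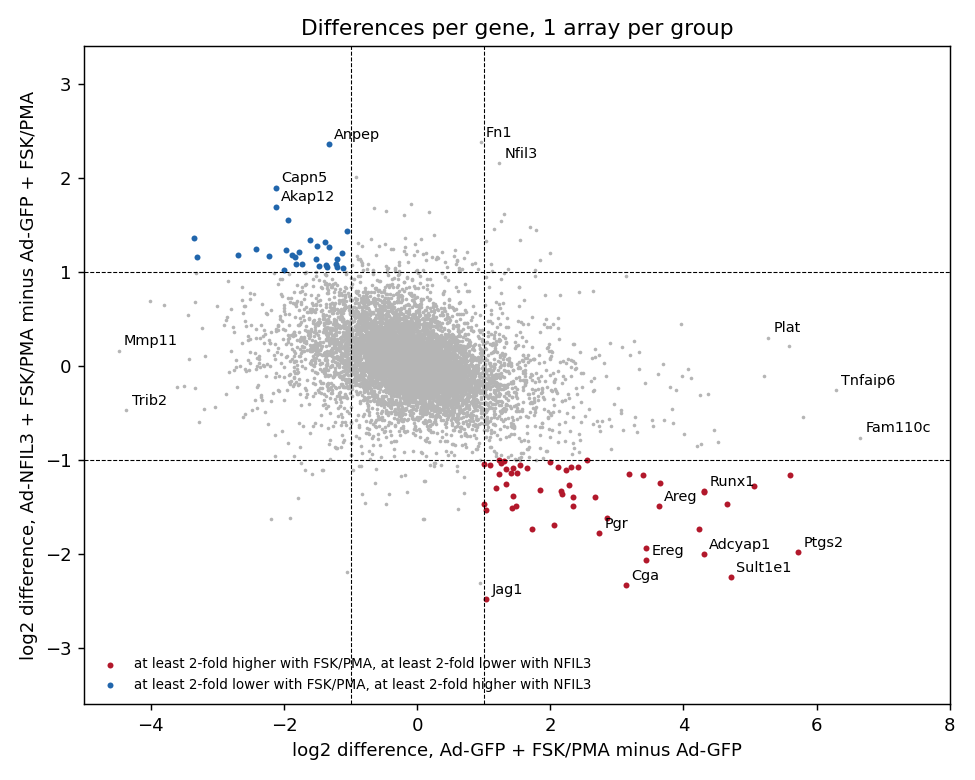
Log2 difference per gene with FSK/PMA (x axis, Ad-GFP with FSK/PMA minus Ad-GFP) against that with NFIL3 (y axis, Ad-NFIL3 minus Ad-GFP, both with FSK/PMA), 1 point per gene measured in both comparisons. Dashed lines mark 2-fold; 53 red points were higher with FSK/PMA and lower with NFIL3, and 30 blue points the reverse.

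Among the genes higher with FSK/PMA, the median share of the log2 difference left with NFIL3 was 84.2%, with quartiles of 67.1% and 102%, and among the genes lower with FSK/PMA it was also 84.2%, with quartiles of 65.1% and 101%. Chance errors of the control and FSK/PMA arrays enter this share, over genes selected for their FSK/PMA difference, and no value was computed for an absent NFIL3 effect. No group had Ad-NFIL3 without FSK/PMA. The share therefore mixes any effect of NFIL3 on unstimulated levels with any change in the response. Ptgs2 was still at least 13.3-fold above control with NFIL3, Tnfaip6 was at least 65.1-fold above and Plat was at least 47.4-fold above, while Jag1 was 2.73-fold below control. Both comparisons use the array of Ad-GFP with FSK/PMA, so that its chance errors enter them with opposite signs. Simulated genes with technical noise alone and no effects, which hold no truly responding genes, gave a mean of 0.99 genes raised then lowered (0 to 4 in 100 simulations) and 0.39 the reverse (0 to 3). They gave a covariance of the differences across genes of -0.043, against an observed -0.116. These values used the noise of the FSK/PMA comparison, and with that of the NFIL3 comparison the covariance was -0.023. The simulated correlation of -0.507 follows from the common array and equal noise per array, so it is no test of the observed -0.356. When different probe sets of a gene served the 2 comparisons, which was possible for 2376 genes, 10 or 9 genes were raised and then lowered, against 2.34 or 2.60 for independent sets. The reverse count was 4 or 1 genes, against 2.37 or 1.30. For these genes the covariance was -0.072 or -0.064 with different probe sets, against -0.116 with the same probe set. The correlation was -0.216 or -0.220, against -0.371 or -0.375.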

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

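In this part the tests of a uniformly weaker response, of chance between pools, of stromal cells and of a response to the virus were chosen only after the result was seen; the others were set before. Probe sets left out of the comparisons, because they name no single gene, also differed: of 10216, 226 were at least 2-fold higher and 390 lower with FSK/PMA. With NFIL3, 56 of them were higher and 37 lower. The control probe set for 5S ribosomal RNA, also outside the comparisons, had a signal of 2105 on the NFIL3 array against 1579 on the control array and 1236 with FSK/PMA.

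Ptgs2, Ereg, Pgr and other genes raised by FSK/PMA were lower with NFIL3, 53 genes past 2-fold in both comparisons. If noise of single probe sets on the common array were the only source, different probe sets would bring this count toward that of independent sets. It was then 3.46 or 4.27 times that number, against 5.18 or 5.77 times with the same probe set in both comparisons. The number for independent sets takes no account of the floor, which makes genes bright with FSK/PMA easier to call lower. These values are thus too high, by an amount that was not computed. For the lower value, 9 genes, a counting bound of 1.58 added later exceeds the limit of 1.5, under which noise alone was to be taken as the source. Both values passed the higher limit set beforehand for calling such noise insufficient, but the bound did not. The bound treats genes as independent and leaves out differences between pools. Such noise may thus account for part of the count. For genes lowered then raised the values with different probe sets were 1.68 or 0.77 times. A uniformly weaker response to FSK/PMA would leave the same share of each difference. Around a common share of 84.7%, the residual spread of 163 genes at least 4-fold higher was 2.56 times (95% bootstrap interval 2.06 to 3.19) that of genes without an FSK/PMA difference at the same signal; a first version of this test, replaced because it used probe set disagreement alone and left out differences between cultures, gave 3.36. The test of a uniformly weaker response covers only a response weaker by 1 common share on the log2 scale. Its reference genes were limited to a log2 FSK/PMA difference of 0.5, which limits the error of the common array in them and can raise the ratio. The bootstrap interval covers spread over genes and leaves out differences between pools. A weaker response that differs from gene to gene stays open. Chance between cultures stays open too, because there was 1 array per group. An effect of NFIL3 on the RNA of selected genes is a further hypothesis that these arrays cannot separate from these. Without an Ad-NFIL3 group lacking FSK/PMA, a weaker response also cannot be told from lower levels before the stimulus.

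The unfolded protein and integrated stress response list had a median of -0.41 with NFIL3, below the limits, with 0 of 14 genes past 2-fold. The part of this from the common array stays open: between the NFIL3 and control arrays, which leave that array out, the median was -0.27 at percentile 5.64, inside the limits. A second list of ATF4 target genes that shares no gene with the first had a median NFIL3 difference of -0.46, at percentile 0. Of its 31 values 28 were below 0, with 1 gene at least 2-fold lower, and its median with FSK/PMA was 0.70. This difference uses the common array too, and no percentile was computed without that array. Among random lists matched on the FSK/PMA difference, which use that array as well, the median of the second list was also at percentile 0. Between the NFIL3 and control arrays most of its measured genes were higher, such as Mthfd2 at 6.59-fold, and others were lower, such as Pck2 at 3.90-fold. A list of 18 other endoplasmic reticulum chaperone genes had a median of -0.02 at percentile 59.1, so these 18 were not lower as a set. That does not cover the chaperone genes of the first list, such as Pdia4 at 1.25-fold lower and Sdf2l1 at 1.12-fold higher. A lower ATF4 response than on the FSK/PMA array is a hypothesis, and the part of the common array in it stays open. Nor can it be told from a lower level before the stimulus, since no group had Ad-NFIL3 without FSK/PMA. The lower values of the second list were led by Slc1a4 at 2.21-fold lower and Vldlr at 1.95-fold lower, both chosen after their values were seen. Against the control array Slc1a4 was 1.28-fold higher and Vldlr was 1.78-fold lower with NFIL3.

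Fn1, Cald1 and Adamtsl1 were higher with NFIL3, and stromal cells in that pool are a candidate source. Of Col1a1, Col1a2, Col3a1, Dcn and Lum, 1 (Dcn) was at least 2-fold higher. On the NFIL3 array Lum was below the floor at 70.4, and Col1a1 had 1 probe set below it at 121. Col3a1 was at 331 without and 341 with NFIL3, a log2 difference of 0.05. Col1a2, near the floor, differed by 0.25, and by at least 0.64 in a dimmer probe set. Another form of the test, on collagen genes alone, pointed against stromal cells and was withdrawn because of low signals. With Dcn higher, Col3a1 level and the others near the floor, stromal cells and an effect of NFIL3 stay open, and they cannot be told apart here. A stronger response to the virus stays open too: the median of the interferon-stimulated genes, 0.21, lay at percentile 81.5, with members in both directions, such as Psmb8 at 1.58-fold higher and Oas1a at least 1.61-fold lower. Outside that list Ifitm3 was 3.12-fold higher, Ifi27l2b was 2.42-fold higher and the chemokine gene Ccl2 was 2.53-fold and Cxcl1 at least 2.77-fold higher.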

How the results depend on the processing

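Random lists matched on the FSK/PMA difference and the count over genes whose probe sets agree were chosen only after the result was seen. Over all settings no named gene past 2-fold changed direction; 2311 values of named genes stayed on their side of 2-fold, 59 fell under it and 21 passed it. Of list medians, 312 kept their side of the limits, 13 moved outside and 13 inside; of counts, 53 stayed within 1.5 times and 35 did not. No paired analysis was possible because each group had 1 array. Signals near the floor limit all counts, and apart from settings that change the fold or the number of genes by construction, the cause was not tested.

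With the floor at the 25th percentile, NFIL3 gave 545 higher and 236 lower genes, with 101 raised then lowered and 162 lowered then raised, and the interferon median of -0.58 for FSK/PMA lay inside the limits (percentile 3.98). At the 75th percentile FSK/PMA gave 420 higher and 402 lower and NFIL3 gave 36 and 48, with 28 raised then lowered and 5 the reverse. There the clock list stood apart for FSK/PMA (0.50, against -0.17 in the main setting) and NFIL3 (-0.36), and for NFIL3 so did steroidogenesis (-0.17), matrix (-0.22) and progesterone receptor (-0.26) genes. Without floor or filter FSK/PMA gave 1777 and 2258, NFIL3 1507 and 910, with 344 raised then lowered and 716 the reverse, and the interferon median of -0.58 had percentile 3.05. The floor as a pseudocount gave 693 lower with FSK/PMA, and 49 higher and 54 lower with NFIL3, with 30 raised then lowered and 9 the reverse.

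At 1.5-fold FSK/PMA gave 1403 and 2259, NFIL3 640 and 399, with 215 raised then lowered and 297 the reverse; at 3-fold the counts were 285 and 345, and 13 and 18. Different probe sets, the second for FSK/PMA, gave 9 raised then lowered and 1 the reverse, against 14 and 3 with the same probe set.

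The cytokine list for FSK/PMA, above the limits in the main setting, moved inside them with median scaling (0.37), quantile (0.47), loess (0.45) and unmatched lists (0.33). For NFIL3, quantile gave cholesterol -0.12 and progesterone receptor -0.24 outside, heat shock -0.15 inside, and 19 lowered then raised. Loess gave clock -0.20 and progesterone receptor -0.21 outside, heat shock -0.16 inside, and 18 lowered then raised. The mean of probe sets gave cholesterol -0.17 outside and heat shock -0.15 inside. Leaving out probe sets for several transcripts gave steroidogenesis -0.20 outside for NFIL3 and interferon -0.34 inside for FSK/PMA. Unmatched lists put steroidogenesis (-0.17) and cholesterol (-0.14) outside for NFIL3. Lists matched on the FSK/PMA difference put periovulatory (-0.36), immediate early (-0.29) and heat shock (-0.19) inside.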

Other observations

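The tests on ATF4 target and chaperone genes were set before their results were seen, and the genes named here were chosen after their values were seen. The ATF4 target list had a median of 0.70 with FSK/PMA, with members in both directions. Mthfd2, of mitochondrial folate metabolism, was 9.63-fold higher with FSK/PMA, the amino acid transporter gene Slc7a5 was 6.25-fold higher and the threonyl-tRNA synthetase gene Tars1 was 3.18-fold higher. Pck2, Phgdh, Gpt2 and Slc38a2 had log2 differences of -1.44, -0.50, -0.29 and -0.24. With NFIL3, Mthfd2, Slc7a5 and Tars1 were 1.46-fold, 1.54-fold and 1.75-fold lower. The ER chaperone gene Hyou1 was 1.57-fold lower with NFIL3, while Creld2 was 1.54-fold higher.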
